A study of Homo sapiens with 6 samples.

How the data were processed

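Total RNA of Jurkat cells, an established human T cell leukaemia line, was measured on 6 expression arrays, 3 of wild-type (WT) cells and 3 of TAOK3 knockout (KO) cells, and the group of each array was taken from its genotype label. The deposited series table holds 53617 probe rows per array on a log2 scale: the values ran from 0.794 to 13.96 and the array medians lay within 0.1 of each other. The log2 scale was inferred from these values, since no header of the deposited table names the unit. Transcriptome Analysis Console 3.0 is the only tool named, per the submitters' processing notes. The background correction, the normalization, the summary of probes and the genome build are not given in the sources used here, and a normalization that equalizes the arrays would hide a shift shared by all genes. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

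Probe names came from the platform annotation, which listed 16098 of the 53617 rows, each with 1 gene symbol and none with several. The other 37519 rows are unnamed here and stayed out of the comparison of genes. All 16098 Entrez identifiers matched the RefSeq gene table of GRCh38.p14, and 0 symbols had to be replaced. That table served for names, chromosomes and the order of neighbouring genes by their start coordinates, and none of its coordinates is reported. Where a gene had several probes, the probe with the highest mean over all 6 arrays stood for it, which left 14884 genes. A gene was tested when its value reached the 40th percentile of its array on at least 3 arrays, which left 11535 genes.

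The deposited log2 values were not normalized again. KO minus WT was fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p, and this threshold is what "rose" and "fell" refer to. The gene lists, 30 in number, were fixed before the data were examined and hold 1049 different genes, of which 650 were named on the array and 597 were tested. Lists with at least 5 tested members, 29 of them, were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. The camera test was also run with an estimated correlation, and limma's fry was run beside it. The text names TAOK3, the 12 largest rises and the 12 largest falls among genes past the threshold whose KO values lie all above or all below the WT values, and up to 4 members of each list past the threshold, or up to 2 where none passed. Small RNAs, unnamed loci, antisense symbols and receptor segments were not taken for the 24 largest changes, which left out 1 fall and 0 rises. Genes named beyond this rule are said to be so. Genes linked to the Y chromosome and XIST were not reported.

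The precision is limited by the number of arrays. The steps were tested on simulated data for WT against TAOK3 KO over 11535 genes, with 200 genes changed. The fit recovered 67.2% of genes changed by 0.5 on the log2 scale, 100% of those changed by 1 and 98.5% of those changed by 2, with 7 false calls among 184. With no list shifted, 0 lists were called, and a list shifted by 0.3 was found with the preset and with the estimated correlation. With the estimated correlation its camera adjusted p was 0.0466. The simulated genes were independent of each other, so the 0 calls do not show how the preset correlation does with correlated genes. The shift was also larger than that of any real list (largest mean -0.207), and each simulation was run 1 time. The alternatives fixed before the data were examined were quantile normalization, median centring, no filter and a stricter filter at the 60th percentile, a spread estimate with trend and robust settings, no moderation, array weights, the replicate number as a block, the mean of all probes of a gene, a threshold of 2-fold and leaving out each array in turn. Alternatives added after seeing the data left out WT array 1 and KO array 2 together, or took the 75th percentile of each array as a covariate. Plots were drawn with matplotlib 3.10.9.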

Results

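The series compared resting gene expression in wild-type (WT) Jurkat cells, a human T cell leukaemia line, with that in Jurkat cells in which TAOK3, a serine/threonine kinase of the TAO family, was knocked out (KO). Total RNA was measured on 3 WT and 3 KO arrays. Each array gave 53617 log2 values, with medians between 4.74 and 4.79. Pairs of arrays correlated across all rows with r of 0.988 to 0.992 within a group and 0.986 to 0.991 between groups, where rows are not independent replicates. The leading principal component, with 39.8% of the variance, placed the WT arrays at -8.22, -9.49 and -10.9 and the KO arrays at 6.57, 13.3 and 8.72. On the next component, with 23.6%, WT array 1 (9.05) and KO array 2 (10.6) stood apart from the other arrays (-10.7 to -1.90).

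TAOK3 itself showed the largest fall of all tested genes that passed the threshold. Its level was 9.24 ± 0.0338 (SD, n = 3) on the log2 scale in WT and 7.07 ± 0.165 (SD, n = 3) in KO cells, 4.48-fold lower (log2 change -2.16, SE 0.0897, limma with Benjamini-Hochberg adjusted p = 0.000107). The WT arrays read 9.27, 9.24 and 9.20 and the KO arrays 6.89, 7.20 and 7.14. Where the edit lies relative to the probes is not given in the sources used here, so the remaining signal does not tell how much intact transcript was left.

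Loss of TAOK3 came with 316 changed genes among 11535 tested, and falls outnumbered rises, with 230 genes lower and 86 higher in KO cells. The largest rise was in ZNF93, a KRAB zinc finger gene, which went from 4.67 ± 0.14 to 7.21 ± 0.147 (SD, n = 3 each), 5.81-fold. EOMES, a T-box transcription factor of effector and memory T cells, rose 4.29-fold from 6.17 ± 0.0791 to 8.28 ± 0.0321, and GZMK, a serine protease of cytotoxic granules, rose 3.75-fold from 4.51 ± 0.142 to 6.42 ± 0.0731 (SD, n = 3 each). After TAOK3, the largest falls were in SIRPB1, a signal regulatory protein (2.82-fold), TDRD9, a helicase of the germline piRNA pathway (2.73-fold), ANXA5, a phosphatidylserine-binding annexin (2.66-fold), and SEL1L3 (2.66-fold).

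The other genes among the 12 largest rises changed by 0.90 to 1.06 on the log2 scale. They were NUDT19, C8orf88, PRTFDC1, the growth factor gene PDGFC, TMEM62, BCHE, which encodes butyrylcholinesterase, the meiotic gene SYCP2, BORCS7-ASMT and LZTFL1. BORCS7-ASMT is a read-through transcript, and whether its probes also read the genes it spans is not given in the sources used here. The other large falls were in EPHA3, an ephrin receptor (-1.39), STK32B (-1.33), CABCOCO1 (-1.31), the costimulatory receptor ICOS (-1.25), the chemokine receptor CCR4 (-1.24), the complement gene C9 (-1.22) and NETO1 (-1.21). The KO means of ICOS (3.29), EPHA3 (4.15), C9 (4.18), NETO1 (4.14) and STK32B lay below the 40th percentiles of the arrays, which were 4.23 to 4.28, a range of dim probes, so the sizes of these changes are uncertain, and the WT mean of PRTFDC1 (4.26) lay within that range.

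**Figure D1:**
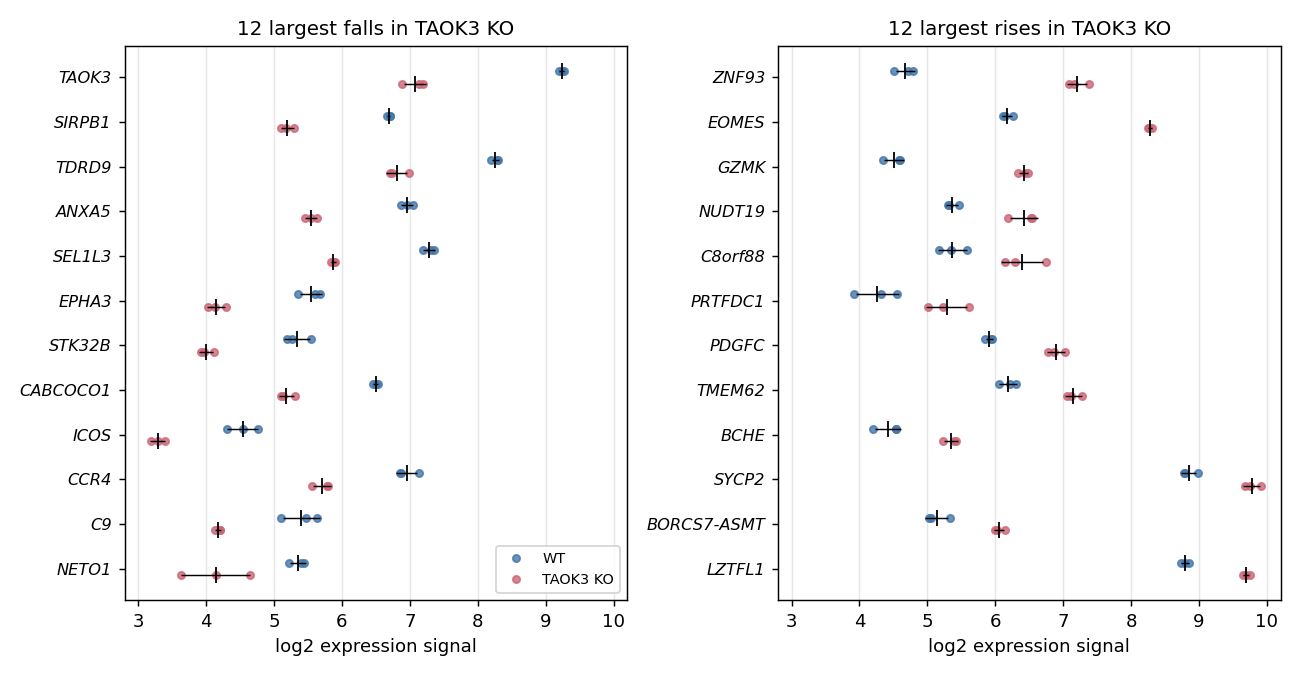
Log2 expression signal of the 12 genes with the largest falls (left) and the 12 with the largest rises (right) in TAOK3 KO against WT cells. Each point is 1 array, with 3 per group, and the vertical tick and horizontal bar give the mean and SD of the group. For all genes shown, the 3 KO values lie on one side of the 3 WT values, from TAOK3 (9.24 in WT, 7.07 in KO) to ZNF93 (4.67 in WT, 7.21 in KO).

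The median size of the change among the 316 genes was 0.53 on the log2 scale, and 6 rises and 23 falls reached 2-fold. The WT and KO values did not overlap for 2472 tested genes (21.4%), where chance gives 10%, and 1750 genes had an unadjusted p below 0.05 in limma against 577 that chance would give. Leaving out 1 array at a time gave 33 to 48 rises and 83 to 141 falls, and leaving out both WT array 1 and KO array 2, a choice made after seeing the data, gave 17 rises and 48 falls. All 316 genes kept their direction in these fits. That outcome was fixed, since the KO values of each lie on one side of its WT values. Besides TAOK3, 30 of the named calls held without each array in turn. Under every alternative that tested them, other than the 2-fold limit, 13 kept an adjusted p below 0.05. These were ZNF93, EOMES, GZMK, PDGFC, LZTFL1, SIRPB1, TDRD9, ANXA5, SEL1L3, EPHA3, CABCOCO1, CD34 and SIT1. Among the other genes named by the rule, 28 calls were lost without at least 1 array (highest adjusted p of 0.0561 to 0.173), and those of ADM, BNIP3L, CTSG, KLF10, KLF2, PGK1, PRTFDC1, SREBF2, THY1, XAF1 and XBP1 were lost whichever array was left out. Those of C8orf88, CCR7, CCR9, CD1D, CD24, CD5, CD6, CD83, DTX1, EGR1, IER3, IL7R, NETO1, PTCRA, RRM1, RSAD2 and SLA were lost without some of the arrays.

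Of 19 tested genes that restrain T cell receptor signalling, 5 fell in KO cells, 0 rose and 14 did not pass. The fallen genes were the adaptor SIT1 (-0.71), the surface receptors CD6 (-0.49) and CD5 (-0.41), and the Src-like adaptors SLA (-0.47) and SLA2 (-0.33), of which SLA2 was added after its values were seen. The call of SIT1 held without each array in turn, while that of CD6 was lost without 4 of the 6 arrays (adjusted p up to 0.0808), that of SLA without 4 (up to 0.0911) and that of CD5 without 3 (up to 0.0693). Adjusted over the list alone, 8 fell. The list's mean was -0.188 and its camera adjusted p was 0.000495, against an adjusted p = 0.513 with an estimated correlation. In the list of the receptor complex and its proximal activators, 0 of 20 members passed in limma, and 5 had an unadjusted p below 0.05. The adaptors LAT and SH2D2A had log2 changes of -0.38 (adjusted p = 0.0985) and -0.35 (adjusted p = 0.286), and 0 members passed when adjusted over the list alone (camera adjusted p = 0.634).

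Receptor and adhesion genes moved in both directions. Of 19 tested members, the chemokine receptors CCR4 (-1.24) and CCR7 (-0.72) and the interleukin receptor IL7R (-0.50) fell, CCR9 (0.74) and CCR8 (0.45, added after its values were seen) rose, and 14 did not pass. Adjusted over the list alone, 2 rose and 8 fell. The mean was -0.167 and the camera adjusted p was 0.0374, with an adjusted p = 0.513 with an estimated correlation. Of 9 tested T cell cytokine genes, only IL16 (-0.59) fell and 8 did not pass, with 2 falls when adjusted over the list alone. That list's mean was -0.17 and its camera adjusted p was 0.0374, against an adjusted p = 0.513 with an estimated correlation. Without WT array 3 the camera adjusted p was 0.0906 for the receptors and 0.192 for the cytokines, and without KO array 2 it was 0.0897 and 0.123. Without KO array 1 it was 0.0657 and 0.0798, without WT array 1 it was 0.0954 for the receptors, and without WT array 2 it was 0.067 for the cytokines.

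Glycolysis and hypoxia genes were the list with the lowest camera p. Of 22 tested members, 4 fell, 0 rose and 18 did not pass, and 20 of 22 had a negative log2 change. The fallen genes were DDIT4, a stress-induced inhibitor of mTORC1 (-0.69), the glycolytic enzyme gene PGK1 (-0.38), the mitophagy receptor gene BNIP3L (-0.35) and the peptide hormone gene ADM (-0.35). The calls of PGK1, BNIP3L and ADM were lost whichever of the 6 arrays was left out, with adjusted p up to 0.149, 0.118 and 0.173, and that of DDIT4 was not. Adjusted over the list alone, 9 fell. The mean was -0.207 and the camera adjusted p was 2.16e-06, against an adjusted p = 0.513 with an estimated correlation. In the cholesterol and lipid synthesis list, only SREBF2, which encodes a transcription factor of sterol synthesis, fell (-0.32) among 28 tested members, and 4 fell when adjusted over the list alone. That list had a mean of -0.108, a camera adjusted p of 0.00333 and an adjusted p = 0.513 with an estimated correlation.

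These 5 lists were the ones called by camera, all of them lower in KO cells. In that fit 0 lists were called higher, with 0 higher at an unadjusted p below 0.05. Under 1 alternative setting the cytosolic ribosomal protein list was called higher (camera adjusted p = 0.011). With an estimated correlation 0 lists were called, and 1, glycolysis and hypoxia, had an unadjusted p below 0.05 (0.0411). The fry test, which does not compare a list with other genes, called the same 5 lists as camera with the preset correlation, all lower. At an unadjusted p below 0.05 it had 8 lists lower and 1 higher, the T-lineage transcription factors. Among the lists that camera did not call, the lowest adjusted p was 0.394.

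Among 25 tested immediate-early and activation genes, the transcription factor gene EGR1 rose (0.45) and IER3 (-0.58), KLF10 (-0.32) and KLF2 (-0.30) fell, while 21 did not pass. Adjusted over the list alone, 3 rose and 4 fell. Probes of IER3 disagreed: the bright ones, with levels of 7.26 to 7.39, had log2 changes of -0.58 to -0.55, and the dimmer ones, at 5.74, had 0.01. Several of the bright and all of the dimmer IER3 probes had identical mean levels and changes, so they may not be separate readings. The mean of all probes counts each of them. A second EGR1 probe, at a level of 4.53, had a log2 change of 0.13. With the mean of all probes both calls were lost, with log2 changes of -0.31 in IER3 (adjusted p = 0.117) and 0.29 in EGR1 (adjusted p = 0.246). Of 19 NF-kB target genes, CD83 rose (0.36) and 18 did not pass, with 1 rise and 2 falls when adjusted over the list alone. The mean of that list was -0.00589, while its median was 0.0529 and camera pointed up (adjusted p = 0.634).

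The transcription factors of the T lineage had 1 rise, EOMES (2.10), and 1 fall, KLF2 (-0.30), among 31 tested, with 1 rise and 3 falls when adjusted over the list alone. Their mean was 0.0204, while their median was -0.0502 and camera pointed down (adjusted p = 0.703). Of 28 genes of immature thymocytes and T cell leukaemia, the chemokine receptor CCR9 (0.74), the recombinase gene RAG2 (0.72) and the antigen-presenting CD1D (0.58) rose. In the same list CD34, a marker of progenitors (-0.88), and CD1B (-0.31, added after its values were seen) fell, 23 did not pass, and 4 rose and 4 fell when adjusted over the list alone. Among 26 Notch genes, PTCRA, which encodes the pre-T cell receptor alpha chain, rose (0.57) and DTX1 fell (-0.57), with 1 rise and 3 falls when adjusted over the list alone. The camera adjusted p was 0.642 for the immature thymocyte list and 0.477 for the Notch list.

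Of 29 genes of TAO kinase partners and the Hippo pathway, the transcription factor TEAD4 (-0.80) and the kinase cofactor MOB1A (-0.53) fell and 27 did not pass, and 2 fell when adjusted over the list alone (camera adjusted p = 0.968). Among 27 MAP kinase genes 0 passed in limma and 9 had an unadjusted p below 0.05. MAP3K8 had a log2 change of -0.34 (adjusted p = 0.104, dim in KO cells at 4.17) and MAP2K4 of 0.30 (adjusted p = 0.329), and 2 rose and 3 fell when adjusted over the list alone. That list's mean (0.00475) and median (-0.00383) differed in sign, and camera pointed up (adjusted p = 0.934). DOCK10, a guanine nucleotide exchange factor, was the 1 member to fall (-0.48) among 24 cytoskeleton and synapse genes, over all genes and adjusted over the list alone (camera adjusted p = 0.394). Of 31 interferon-stimulated genes, RSAD2 (-0.46) and XAF1 (-0.36) fell and 29 did not pass, with 1 rise and 5 falls when adjusted over the list alone (camera adjusted p = 0.934).

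Growth programmes held few calls. RRM1, a subunit of ribonucleotide reductase, fell (-0.53) among 25 replication genes, over all genes and adjusted over the list alone. The mean of that list was 0.004 and its median -0.00243, and camera pointed up (adjusted p = 0.842). In limma, 0 of 34 mitosis genes, 0 of 25 MYC target genes, 0 of 25 ribosomal protein genes and 0 of 13 oxidative phosphorylation genes passed, and 0 of each passed when adjusted over the list alone. Their counts at an unadjusted p below 0.05 were 2, 0, 1 and 0, and their camera adjusted p values were 0.394, 0.394, 0.394 and 0.968. The largest log2 changes in them were 0.16 in KIF18A and 0.15 in NDC80, -0.15 in EIF5A and 0.14 in MYBBP1A, 0.21 in RPS23 and 0.16 in RPL37A, and -0.17 in CYC1 and 0.13 in UQCRB.

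Among 22 genes of the unfolded protein response, DDIT4 (-0.69) and the transcription factor XBP1 (-0.42) fell, over all genes and adjusted over the list alone (camera adjusted p = 0.514). Of 19 heat shock and oxidative stress genes 0 passed in limma, 3 had an unadjusted p below 0.05, and 2 fell when adjusted over the list alone. The metallothionein MT1F had a log2 change of -0.66 (adjusted p = 0.0577) and SRXN1 of -0.39 (adjusted p = 0.0757, camera adjusted p = 0.44 for the list). Of 22 apoptosis regulators 0 passed in limma and 4 had an unadjusted p below 0.05, with BCL2A1 at -0.62 (adjusted p = 0.125, dim in KO cells at 4.11) and BCL2 at -0.24 (adjusted p = 0.219). Of 17 p53 target genes 0 passed and 0 had an unadjusted p below 0.05, with EDA2R at -0.30 and TP53I3 at 0.17. Adjusted over the list alone, 0 members of both lists passed, and the camera adjusted p was 0.49 for apoptosis and 0.968 for p53, where camera pointed up while the mean (-0.00864) and the median (-0.0134) were negative.

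Markers of cytotoxic and NK cells did not move together. Of 14 tested members GZMK rose (1.91), the cystatin CST7 (-0.82) and the cathepsin CTSW (-0.73) fell, and 11 did not pass, with 2 rises and 4 falls when adjusted over the list alone. The mean of that list was 0.0103, its median was -0.0867 and camera pointed down (adjusted p = 0.411). CD24 rose (0.56) among 17 B cell markers, from a WT mean of 4.06 that is below the 40th percentile of each WT array, with 1 rise and 3 falls when adjusted over the list alone. CTSG, a protease gene, fell (-0.37) among 11 myeloid markers, and the surface glycoprotein THY1 fell (-0.39) among 9 markers of adherent cells, each also the 1 fall when adjusted over the list alone. The adherent list had a mean of -0.0455 and a median of 0.0157. Of 9 erythroid and megakaryocyte markers 0 passed in limma or adjusted over the list alone, and 1 had an unadjusted p below 0.05. GP9 had a log2 change of -0.22 and EPB42 of 0.17, and camera pointed up while the mean (-0.00704) and the median (-0.00803) were negative. The camera adjusted p was 0.514 for B cell, 0.703 for myeloid, 0.703 for adherent and 0.968 for erythroid markers. Only 4 genes of the antigen presentation list were tested, too few for camera, and 0 passed over all genes in limma, with 1 at an unadjusted p below 0.05 and 1 rise when adjusted over the list alone. ERAP2 had a log2 change of 0.26 (adjusted p = 0.134) and ERAP1 of 0.13 (adjusted p = 0.333).

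**Figure D2:**
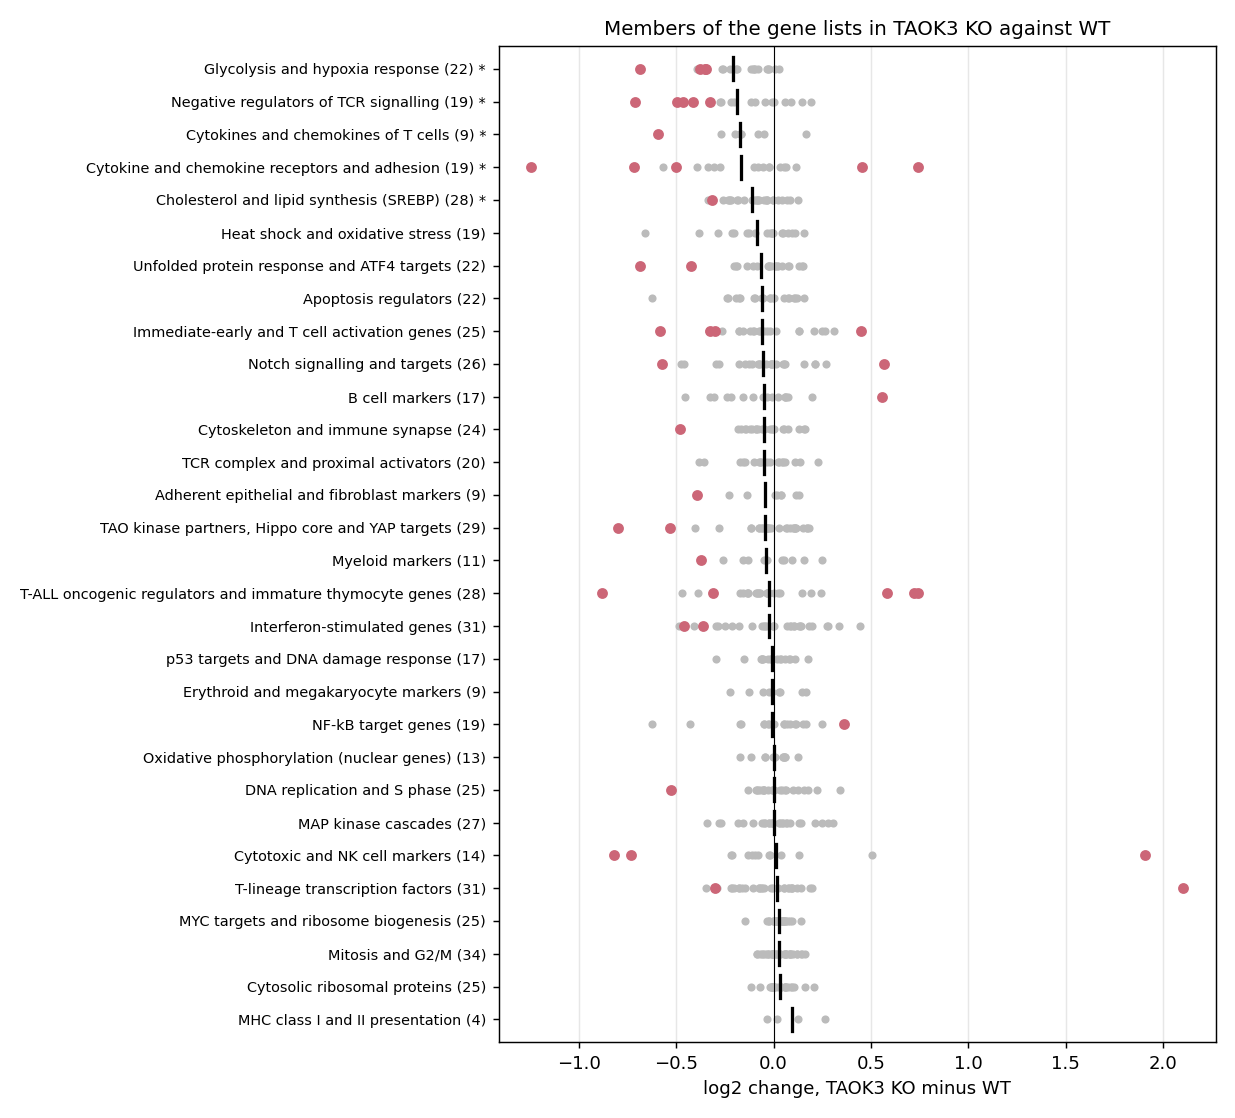
Log2 change (TAOK3 KO minus WT) of each tested member of the 30 gene lists, with the number of tested members in brackets. Each point is 1 gene, red where its adjusted p was below 0.05, the black bar is the mean of the list, and an asterisk marks the 5 lists called by camera with the preset correlation. The 5 called lists have means from -0.207 to -0.108, and 0 of them was called with an estimated correlation.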

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

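The comparison of genes left out 37519 probe rows that the platform annotation does not name here, and these rows hold signal that differs between the groups. Of them, 20197 passed the same filter, and limma found 32 higher and 52 lower in TAOK3 KO cells at an adjusted p below 0.05. The change reached 2-fold in 19 of the higher and 19 of the lower rows. Probes 17118514 and 17118520 held the same values and went from 3.61 in WT to 6.16 in KO cells (log2 change 2.55, SE 0.209, adjusted p = 0.0125 in limma). Probe 17121988 went from 5.95 to 3.42 (-2.54, adjusted p = 0.00262), and probe 16686271 from 9.10 to 6.58 (-2.52, adjusted p = 0.0226). The means of 3.61 and 3.42 lie in the range of dim probes, below the 40th percentile of each array (4.23 to 4.28), so the sizes of the changes of those 3 probes are uncertain. The probes were picked by size after their values were seen.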

How the results depend on the processing

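The TAOK3 change kept its direction and its side of the threshold under all alternatives, from -2.23 to -2.07. Against 86 rises and 230 falls, counts were 57 and 138 with no filter, 195 and 374 with trend and robust settings, 32 and 56 with no moderation, and 6 and 23 at 2-fold or more. Leaving out 1 array in turn gave 33 to 48 rises, 83 to 141 falls and 3 to 5 lists, with fewer samples in each fit. Of the choices made after seeing the data, leaving out WT array 1 and KO array 2 together gave 17 and 48, and the 75th percentile as a covariate gave 57 rises, 181 falls and 3 lists. Of the 5 lists, 3 were called with array weights and 0 with an estimated correlation. The cause of these shifts was not tested. Whether equal replicate numbers mark paired arrays is not stated in the labels. Deviations from the group means correlated at -0.26, -0.17 and 0.03 for equal numbers. Between groups they correlated most for WT array 1 with KO array 2 (0.3). So few arrays do not settle whether any of them are paired. With the replicate block, 35 rises and 84 falls were called, all 119 among the 316, and 4 lists. All of the 316 genes that were tested kept their direction under every setting. In fits that left out or weighted arrays, or changed only the filter, the spread or the block, that was fixed in advance. The direction could differ only with changed normalization, the mean of probes or the covariate. Rises made up 23.7% to 36.4% of calls in the fits without a 2-fold limit (27.2% as reported). For named genes, 267 results under alternatives dropped out of the threshold and 7 entered it. For lists 20 dropped out and 1, the cytosolic ribosomal proteins, entered. A further 38 list results and 1 of a gene (UQCRB) changed sign while past the threshold in neither fit, and were counted as not changed. Besides TAOK3, 13 of 58 named calls passed under every alternative other than the 2-fold limit, 30 passed without each array in turn, and 14 passed under at most 7 alternatives. Quantile normalization, median centring, the stricter filter and the mean of probes left the counts of genes and lists within 1.5 times. Camera was not run without moderation, since it moderates the spread itself. Dim genes are limited by signal over background.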

Other observations

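Some genes outside the lists with a role in T cells or a large change are given here as single values, picked after their values were seen and not tested as a group. Of genes for surface molecules, the costimulatory receptor CD27 fell by 0.86 on the log2 scale, the ectoenzyme CD38 by 0.74, LY9, a receptor of the SLAM family, by 0.78, and SIRPG, a receptor for CD47, by 1.19. The adhesion molecules ALCAM (-1.01) and PECAM1 (-0.82), the glycoprotein GPA33 (-0.93) and the scavenging chemokine receptor ACKR3 (-0.88, dim in KO cells at 4.22) fell as well, each of these 8 genes with a limma adjusted p between 0.00102 and 0.0172. Others rose, among them the transmembrane adaptor TRAT1 (0.46) and the receptor GPR174 (0.28). GFRA1, a co-receptor for GDNF (0.84), VIPR2, a receptor for vasoactive intestinal peptide (0.76), and the nuclear receptor RORB (0.80) rose too. The limma adjusted p was 0.0491 for GPR174, the smallest change among the 316 genes. It was 0.0153 for TRAT1 and between 0.000906 and 0.00821 for GFRA1, VIPR2 and RORB.

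The test over other splits of the arrays and the test of zinc finger genes as a class were chosen after the results were seen, and so was the covariate fit. The test on neighbours of the changed genes was also added late, after the window test, with its bounds set before its value was seen. Decision rules of other tests were changed after first values were seen. The window test met its bound as first written, by 1 standard error and not by 2, and is now read as undecided because of the correlation between neighbours. The chromosome 19 test was moved to genes not named ZNF, with the same verdict, and the class test was made to require separated arrays, which turned a verdict for the class into an open one.

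For the 316 genes that differed, of the 10 splits of the 6 arrays into 3 and 3, only the real 1 gave 316 genes and the highest of the others gave 0 (the others had 246 to 957 genes at an unadjusted p below 0.05), and 10 splits are too few for a share under 0.05. Whether a difference in signal distribution between arrays contributes stays open. The median change of these genes was 0.521 with the 75th percentile as a covariate and 0.528 without it (SE 0.0221), and 219 stayed past the threshold. That percentile overlapped between the groups (6.56 to 6.60 in WT and 6.56 to 6.67 in KO arrays). The genes were picked without the covariate, partly for a small spread within groups, so a similar median was likely in any case. Copy number differences of segments of several genes as the cause of most of the changes are argued against. The 4 nearest tested neighbours of a changed gene had a median change of only 0.0189 in its direction (SE 0.00503, 313 genes), against 0.528 for the changed genes. Shorter segments are not addressed by this median over genes. Whether single segments differ stays open: the largest median of 25 neighbouring genes was 0.168 (SE 0.0281), on chromosome 19 from ZNF749 to ZSCAN18, 6 of 1000 shuffles of the gene order gave one as large, and neighbouring genes correlated at 0.0809 against at most 0.028 in the shuffles. Differences between the lines unrelated to TAOK3, which may have arisen while the KO cells were made and grown, were not tested and coincide with the knockout in these groups.

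GZMK and EOMES rose together, and cytotoxic or NK cells in the KO cultures are a candidate source. Such cells would raise the other markers of the list too, but the median of the 14 other named members, of which 13 were tested and HOPX lay below the filter, was -0.0867 (98.7% interval -0.218 to 0.0401), with PRF1 at -0.22, GNLY at -0.11 and NKG7 at -0.02. The highest was SLAMF7 at 0.50 (adjusted p = 0.219 in limma), far below GZMK at 1.91. The list has 27 members, of which only 15, GZMK among them, were named on the array, so the others were not assessed. A hypothesis that stays open is that the Jurkat cells themselves, all or some of them, express more EOMES and GZMK, and arrays of bulk RNA do not tell these apart.

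Among 405 tested ZNF genes 8 rose and 2 fell, against 78 rises among 11130 others (odds ratio 2.85, 95% interval 1.18 to 5.96, Fisher's exact p = 0.0105 over genes, which are not independent). The 8 rises became 4, 3 and 5 without WT array 1, 2 or 3, 6, 3 and 4 without KO array 1, 2 or 3, and 1 without both WT array 1 and KO array 2. The median change of the class was 0.0355, above that of 10000 random lists (p = 1e-04, the smallest they can give), but scored per array the class overlapped between the groups (exact permutation p = 0.5, two-sided, where 0.1 is the smallest possible), and the difference from other genes went from 0.0389 to 0.0132 without KO array 2 and to 0.012 with the 75th percentile as a covariate, so neither a rise of the class nor array signal distribution as its source is settled. A gain of all of chromosome 19, which holds 6 of the 8 risen genes, is argued against: its 724 other genes had a median of -0.0131 (95% interval -0.0234 to -0.00507), and its 185 ZNF genes 0.0513. A gain of a segment rich in ZNF genes may still contribute, since the window from ZNF749 to ZSCAN18 (0.168) left it undecided. Whether ZNF probes, that of ZNF93 among them, also read related ZNF transcripts was not tested.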
